A study of Mus musculus with 12 samples.

How the data were processed

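Gene expression was measured in total liver RNA of 12 mice on Affymetrix mouse Gene Level 1.0 ST arrays, 1 array per mouse as far as the labels show. The mice fell into 4 groups of 3, taken from the sample titles: euthyroid controls (replicates 13, 14 and 15), hypothyroid controls (17, 18 and 20), euthyroid mutants (2, 3 and 4) and hypothyroid mutants (5, 6 and 7). The mutants are the L-NCoR∆ID mice of the series' design text, in which the nuclear receptor corepressor NCoR is altered in the liver. Per the labels' protocols, RNA was isolated with Trizol, purified on RNeasy columns, and 200 ng was made into terminal-labelled cDNA. The deposited values are log2 signals from RMA, per the submitters' processing notes, which give neither its version nor its options. The feature build and the scan dates are not given in the sources used here, so no array batch could be tested.

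The table held 35557 transcript clusters on 12 arrays, with 0 missing values. The platform annotation gave exactly 1 gene symbol to 21789 clusters (19938 genes, 999 of them with more than 1 cluster), several symbols to 1621 and no listed gene to 12147. Entrez identifiers of 21698 clusters were found in a RefSeq gene table of assembly GRCm38.p6, which served for names alone. Tests of genes used the 21789 clusters with 1 symbol and no filter on level, and each cluster was tested on its own. The clusters with several symbols or none were tested apart and no gene was named from them. No cluster of the annotation was named Ncor1, so the level of the altered gene itself was not analysed here.

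Differences were computed with limma 3.58.1 in R 4.3.3 on the deposited log2 values. A linear model with 4 group means was fitted to all 12 arrays, with moderated variances (prior degrees of freedom 6.83, residual degrees of freedom 8) and Benjamini-Hochberg adjustment within each comparison. A cluster was called at an adjusted p under 0.05. The comparisons were mutant against control in each thyroid state, hypothyroid against euthyroid in each genotype, the difference between thyroid states of the mutant effect, and the mutant effect averaged over thyroid states. Adjusted p-values of genes are from limma throughout, standard errors (SE) are those of its fit, and every group held 3 mice. The p-values of genes set a difference against the spread between the mice of a group. Those of the camera tests of gene lists compare list members with other genes and do not measure replication over mice. The number of arrays limits the precision.

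The gene lists, the rule for naming genes, the comparisons and most alternative settings were chosen before the data were examined. The rule named the 8 largest rises and 8 largest falls among the called clusters of each comparison whose groups did not overlap, the 2 to 4 most changed called members of each list described (or 2 members as values where none was called), and Thra, Thrb, Thrsp, Dio1, Me1, Gpd2 and Klf9. Genes outside the rule were chosen after their values were seen, and the text says which. Of 28 lists fixed for liver and thyroid hormone, 25 were tested with camera (preset correlation 0.01, directional), using for each gene the cluster with the highest mean. Erythroid, adipocyte and sex chromosome markers were listed as values and not tested. Each list was also tested with the correlation estimated per list and with fry, and its members were also adjusted over the list alone. Several lists share members; 14 of the thyroid hormone induced genes, for example, stand in other lists too.

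The mutant effect on thyroid-responsive genes was measured by cross-fitting: genes called in hypothyroid against euthyroid controls were picked without 1 control array, and the mutant effect was measured against the array left out. The effect is given as a median over the picked genes. Its exact permutation p is that of the mean over those genes, which were not picked again for each relabelling. Correlations of log2 differences are across genes, which are not independent replicates. They stand beside those of 20 simulations of unchanged groups that share the same control arrays. The simulated noise was independent for each gene and array. Means of list members per mouse were compared between genotypes within thyroid state by a two-sided exact permutation test over 400 relabellings, whose smallest p is 0.005.

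The fit was tested on simulated data with 200 of 21789 clusters changed. Noise was drawn independently for each cluster and array at the cluster's real spread. Outlying arrays and differences in signal range were not simulated, so the shares in the real data may be lower. For mutant against control in euthyroid mice it recovered 15.5% of 1.5-fold changes, 81% of 2-fold changes and 99% of 4-fold changes. For hypothyroid against euthyroid controls the shares were 19%, 80.5% and 98%.

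Alternatives were quantile normalization between arrays, median centring, clusters above the median level, every cluster of the table, a fold limit of 1.5, array weights, a variance trend with robust moderation, the compared groups alone, and each array left out in turn. Chosen after the data were seen were a fit without both outlying arrays (control euthyroid replicate 14 and mutant hypothyroid replicate 7), a fit with the SD of each array as a covariate, and the exact permutation of list means per mouse. Array SD differed between groups, so this covariate takes up part of a group difference and can make its estimate less precise. A call lost with the covariate therefore does not show that signal range was the cause. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.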

Results

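Liver RNA of 12 mice was compared in a design of genotype by thyroid state, with 3 mice in each of 4 groups. The series asks, per its design text, what part the corepressor NCoR plays in genes that thyroid hormone switches on and in genes that it switches off. Array medians lay between 4.16 and 4.32 (log2), and Xist was high (9.25 to 9.97) while the Y-linked genes Eif2s3y, Kdm5d and Uty were low (1.57 to 2.54) on every array. That is the pattern of female mice, while the labels do not give the sex. The arrays differed in their range of signal. The SD of log2 values over all clusters averaged 2.26 (SD 0.0338, n = 3) in euthyroid controls, 2.29 (SD 0.00448) in hypothyroid controls, 2.28 (SD 0.024) in euthyroid mutants and 2.34 (SD 0.018) in hypothyroid mutants. Control euthyroid replicate 14 (54.76) and mutant hypothyroid replicate 7 (-40.15) lay at opposite ends of the first principal component.

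In euthyroid mice, genes of lipid synthesis were the main group that was higher in mutant than in control liver. Pnpla3, which encodes a lipid droplet protein, rose 6.09-fold, from 4.84 (SD 0.156, n = 3) to 7.45 (SD 0.505, n = 3) on the log2 scale. Thrsp, a lipogenic gene induced by thyroid hormone, rose 4.21-fold (log2 difference 2.07 ± 0.3 SE, adjusted p = 0.0107), and the fatty acid elongase Elovl6 rose 4.01-fold (adjusted p = 0.0206). Malic enzyme, Me1, which supplies NADPH for fatty acid synthesis, rose by 1.68 ± 0.24 in one cluster and by 1.55 ± 0.222 in another. Fatty acid synthase, Fasn, rose by 1.22 ± 0.21 (adjusted p = 0.0333) and the desaturase Scd1 by 1.12 ± 0.174 (adjusted p = 0.0171). Of the cholesterol pathway, Sqle (1.24 ± 0.212) and Mvd (1.08 ± 0.191) rose. Ehhadh, an enzyme of peroxisomal fatty acid oxidation, rose by 1.48 ± 0.213, the carboxylesterase Ces2a by 1.13 ± 0.14 and the serpin Serpina12 by 1.93 ± 0.273. The largest rises were those of Gm21286 (3.56 ± 0.528), the sulfotransferase Sult2a3 (3.04 ± 0.516) and the glucuronosyltransferase Ugt2b37 (3.01 ± 0.486), members of gene families whose copies can share probes, so these stay uncertain. The only fall was that of Etnppl, a phospholyase, by 1.21 ± 0.189 (adjusted p = 0.0176). Dio1, the liver deiodinase that activates thyroid hormone, differed by 1.05 ± 0.21 (adjusted p = 0.0773) and was not called, nor were Gpd2 (0.59), Klf9 (-0.65) and the receptors Thra (-0.30) and Thrb (0.11). In limma, 28 clusters of 26 genes were called, 27 higher and 1 lower (38 and 7 after quantile normalization). A covariate for array SD gave 28 calls, 19 higher and 9 lower, of which 18 were shared. The 28 calls of the main fit all had groups that did not overlap, against 10.4% of all clusters and 10% by chance. Calling picks differences that are large for their spread, so this is no separate support, here or in the later comparisons. The count was 192 without control euthyroid replicate 13, 8 without replicate 14, 8 without mutant euthyroid replicate 2 and 6 without replicate 4. Of the named calls, those of Pnpla3 and Ces2a alone were kept whichever array was left out.

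The fixed lists place these genes in pathways. Of 25 measured genes of fatty acid and triglyceride synthesis, 7 rose over all genes and 14 when adjusted over the list alone, 0 fell, and the list as a whole rose (camera adjusted p = 3.35e-21, and adjusted p = 0.10 with an estimated correlation). Of 20 genes of cholesterol synthesis and uptake, 2 rose over all genes and 11 when adjusted over the list alone (camera adjusted p = 1.36e-17, and 0.18 with an estimated correlation). Of 16 targets of LXR, the oxysterol receptor, 2 rose (Scd1 and Fasn), with 5 adjusted over the list alone (camera adjusted p = 8.47e-08, and 0.18 with an estimated correlation). Kupffer cell and macrophage markers were higher as a list (camera adjusted p = 1.15e-09, and 0.27 with an estimated correlation), with 0 of 12 called over all genes and 5 adjusted over the list alone. Their largest differences were those of Cd5l (1.17 ± 0.283, adjusted p = 0.188) and Vsig4 (1.13 ± 0.4, adjusted p = 0.536). Cell cycle genes were higher as a list (camera adjusted p = 3.04e-05, and 0.35 with an estimated correlation), led by Mcm6 (0.83) and Mcm3 (0.57), with 0 called either way and a list p of 0.102 (camera, adjusted) without mutant euthyroid replicate 4. Clock genes were lower (camera adjusted p = 0.0185, and 0.63 with an estimated correlation), led by Dbp (-1.51) and Per1 (-1.07), with 0 called. Their adjusted p lay above 0.05 without control euthyroid replicate 15 (adjusted p = 0.187), mutant euthyroid replicate 2 (0.0705) or replicate 4 (0.0934). PPARA targets (camera adjusted p = 0.0108), oxidative phosphorylation (0.00756), female-biased genes (0.0211) and xenobiotic metabolism (0.0459) also passed as higher, and with an estimated correlation their adjusted p was 0.67, 0.67, 0.50 and 0.67. Without control euthyroid replicate 14 none of these last 4 passed (camera adjusted p 0.574, 0.563, 0.0847 and 0.164), nor after quantile normalization (0.149, 0.159, 0.0747 and 0.149). With array SD as a covariate the p was 0.244 for PPARA targets and for oxidative phosphorylation and 0.589 for xenobiotic metabolism. Without mutant euthyroid replicate 4 the p of PPARA targets was 0.0512 and that of female-biased genes 0.13. For female-biased genes it was 0.162 without control euthyroid replicate 13 and 0.0529 without mutant euthyroid replicate 2. The p of xenobiotic metabolism was also 0.426 without control euthyroid replicate 15, 0.0507 without control hypothyroid replicate 17, 0.0536 and 0.651 without mutant euthyroid replicates 2 and 3, and 0.0541, 0.055 and 0.0668 without mutant hypothyroid replicates 5, 6 and 7. Genes induced by thyroid hormone did not pass as a list (camera adjusted p = 0.189), with 2 of 22 higher over all genes, and 5 higher and 3 lower when adjusted over the list alone. Of the called members, 5 of 7 in fatty acid synthesis, 0 of 2 in cholesterol synthesis and 1 of 2 among LXR targets stayed called with array SD as a covariate, and 3, 0 and 0 without both outlying arrays. In this comparison, array SD averaged 2.28 in mutants and 2.26 in controls, among which replicate 14 had the lowest (2.22).

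In hypothyroid mice the lipogenic genes were again higher in mutants, and several genes that hypothyroidism lowered in controls were higher too. The desaturase Scd2 rose 5.01-fold, from 5.20 (SD 0.28, n = 3) to 7.52 (SD 0.147, n = 3), Thrsp rose 4.48-fold (2.16 ± 0.3, adjusted p = 0.00521) and Elovl6 3.94-fold (1.98 ± 0.32, adjusted p = 0.0154). Sult2a8, a sulfotransferase of a family with near-identical copies, rose 11.3-fold (adjusted p = 0.00135). Me1 rose by 1.73 ± 0.24 in one cluster and by 1.58 ± 0.222 in another, Fasn by 1.38 ± 0.21 and Ehhadh by 1.38 ± 0.213. Gpd2, the mitochondrial glycerol phosphate dehydrogenase that thyroid hormone induces, rose 2.99-fold (1.58 ± 0.208, adjusted p = 0.00432). Pdk4, a kinase that shuts off pyruvate dehydrogenase, rose by 1.81 ± 0.353 and glycogen phosphorylase, Pygl, by 0.75 ± 0.14. Ces2a (1.81 ± 0.14), Cyp3a11 (1.39 ± 0.191), Cyp3a25 (0.89 ± 0.13), the bile acid enzyme Cyp27a1 (0.92 ± 0.156), Sqle (1.32 ± 0.212), Paqr9 (1.97 ± 0.259) and Rarres1 (adjusted p = 0.0128) rose as well. The orphan receptor gene Nr4a1 fell by 2.66 ± 0.372 (adjusted p = 0.00521) and the keratin gene Krt23 fell by 2.51 ± 0.232 (adjusted p = 0.000143). Smaller falls were those of Pcp4l1 (-1.64 ± 0.276), Lce1c (-1.13 ± 0.215), Zfp395 (-0.91 ± 0.13, and -0.87 in another cluster, not called), Abhd2 (-0.89 ± 0.172), the noncoding Rian (-0.87 ± 0.146) and Hykk (-0.79 ± 0.149). Dio1 lay below the array medians in both groups (3.23 and 3.25) and differed by 0.02. Thra (-0.27), Thrb (0.07) and Klf9 (-0.62) were not called. In limma, 57 clusters of 55 genes were called, 47 higher and 10 lower (56 and 5 after median centring), all with groups that did not overlap, against 22.5% of all clusters and 10% by chance. A covariate for array SD gave 9 calls, 5 higher and 4 lower, of which 7 were shared, and with the compared groups alone 174. Array SD did not overlap between these groups (2.288 to 2.296 in controls, 2.316 to 2.35 in mutants). The covariate thus cannot be told apart well from genotype here, and lost calls may reflect lost precision. The count was 133 without control euthyroid replicate 13, 119 without replicate 14, 21 without control hypothyroid replicate 17, 34 without replicate 20, 29 without mutant hypothyroid replicate 6 and 25 without replicate 7. Of 25 named calls, 12 were kept whichever array was left out, those of Sult2a8, Scd2, Thrsp, Paqr9, Ces2a, Nr4a1, Krt23, Zfp395, Me1, Gpd2, Cyp3a11 and Cyp3a25.

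Among the lists in hypothyroid mice, fatty acid and triglyceride synthesis rose (camera adjusted p = 1.42e-21, and 0.097 with an estimated correlation), with 6 of 25 genes higher over all genes and 16 adjusted over the list alone. Cholesterol synthesis and uptake rose (5.24e-09, and 0.33 with an estimated correlation), with 1 of 20 higher over all genes and 9 adjusted over the list alone. LXR targets rose (1.24e-06, and 0.32 with an estimated correlation), with 1 of 16 higher and 7 adjusted over the list alone. Clock genes fell as a list (camera adjusted p = 0.000801, and 0.33 with an estimated correlation), led by Dbp (-1.83) and Per1 (-1.25), with 0 called over all genes and, adjusted over the list alone, 6 lower and 1 higher. Xenobiotic metabolism rose (1.28e-05, and 0.33 with an estimated correlation), with 3 of 23 genes higher, Ces2a, Cyp3a11 and Cyp3a25, and, adjusted over the list alone, 6 higher and 1 lower. Bile acid synthesis and transport rose (0.00367, and 0.33 with an estimated correlation) with 1 of 21 genes called, Cyp27a1, and 5 adjusted over the list alone. Genes induced by thyroid hormone were higher as a list (camera adjusted p = 0.0162, and 0.33 with an estimated correlation), with 3 of 22 higher, Thrsp, Me1 and Gpd2, and, adjusted over the list alone, 7 higher and 5 lower. Without control hypothyroid replicate 20 the list's p was 0.138, and after quantile normalization 0.0811. Kupffer cell markers (0.00182), PPARA targets (0.0135) and oxidative phosphorylation (0.00445) passed as higher, with adjusted p of 0.55, 0.62 and 0.56 with an estimated correlation. Of Kupffer cell markers 0 were called, with C1qb and Adgre1 both at 0.63, and of PPARA targets Pdk4 and Ehhadh rose. Without mutant hypothyroid replicate 6 the p of Kupffer cell markers and of PPARA targets was 0.192, and without replicate 5 that of oxidative phosphorylation was 0.0507. After quantile normalization the p of PPARA targets and of oxidative phosphorylation was 0.15. Hypothyroid mutants had the highest mean array SD (2.34, against 2.29 in hypothyroid controls). Of the called members, 1 of 6 in fatty acid synthesis (Scd2) and 1 of 3 in xenobiotic metabolism (Ces2a) stayed called with it as a covariate, and 0 in the cholesterol, LXR, bile acid, PPARA and thyroid hormone induced lists. Without both outlying arrays 4 of the 6 in fatty acid synthesis stayed called, and 0 in the cholesterol, LXR and bile acid lists. With array SD as a covariate the p was 0.847 for Kupffer cell markers, PPARA targets and oxidative phosphorylation, 0.579 for bile acid genes, 0.0501 for xenobiotic metabolism and 0.0519 for genes induced by thyroid hormone.

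Averaged over both thyroid states, the mutant effect was best resolved for lipid synthesis. The mean log2 level of the fatty acid and triglyceride list was 8.66 (SD 0.0822, n = 3) in euthyroid controls, 8.82 (SD 0.287) in hypothyroid controls, 9.45 (SD 0.0757) in euthyroid mutants and 9.61 (SD 0.188) in hypothyroid mutants. The mutant difference was 0.79 ± 0.104 SE (exact permutation p = 0.005, the smallest possible, 0.05 after adjustment over 25 lists), and each of the 6 mutants lay above each of the 6 controls. By this permutation 0 of the 25 lists had an adjusted p under 0.05, and that of the clock list was 0.0972. Cholesterol synthesis, LXR targets, Kupffer cell markers and genes induced by thyroid hormone (0.238 ± 0.0739 SE) also had 0.05, with unadjusted p of 0.01, 0.005, 0.01 and 0.01. The smallest p of 0.005 limits this test, since a single list at that value cannot pass after adjustment over 25 lists. Of the 25 genes, 14 rose over all genes and 17 adjusted over the list alone, with Thrsp (2.12 ± 0.212, adjusted p = 0.000139), Elovl6 (1.99 ± 0.226), Scd2 (1.93 ± 0.13, adjusted p = 2.8e-06) and Pnpla3 (1.85 ± 0.176) at the top. The list passed with camera (adjusted p = 9.91e-24, and 0.074 with an estimated correlation). Cholesterol synthesis rose (4.77e-15, and 0.26 with an estimated correlation), with 8 of 20 higher, among them Sqle (1.28), Pmvk (0.92), Hmgcs1 (0.90) and Cyp51 (0.89), and 13 adjusted over the list alone. LXR targets rose (1.75e-08, and 0.18 with an estimated correlation), with 5 of 16 higher, among them the phospholipid transfer protein Pltp (1.53 ± 0.277) and lipoprotein lipase, Lpl (1.35), and 9 adjusted over the list alone. With array SD as a covariate 6 of the 14 fatty acid genes, 1 of the 8 cholesterol genes (Sqle) and 1 of the 5 LXR targets (Fasn) stayed called. Without both outlying arrays 11, 5 and 2 did, and Hmgcs1, Pltp and Lpl were lost. Kupffer cell markers rose (1.14e-07, and 0.33 with an estimated correlation), with 1 of 12 called, Adgre1 (0.66 ± 0.145, adjusted p = 0.0427), and 8 adjusted over the list alone. The call of Adgre1 was kept without control euthyroid replicate 13, mutant euthyroid replicate 2 or mutant hypothyroid replicate 5 and lost without any other single array, without both outlying arrays (0.163) and with array SD as a covariate (0.578). Clock genes fell as a list (0.000796, and 0.33 with an estimated correlation), with Per1 (-1.16 ± 0.234, adjusted p = 0.0265) the 1 call and, adjusted over the list alone, 10 lower and 3 higher. The call of Per1 was lost without control euthyroid replicate 14 (0.0608), control hypothyroid replicates 17 (0.0888) and 18 (0.0625), mutant euthyroid replicates 2 (0.067) and 4 (0.0512), and mutant hypothyroid replicates 5 (0.0613) and 6 (0.0781).

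**Figure D1:**
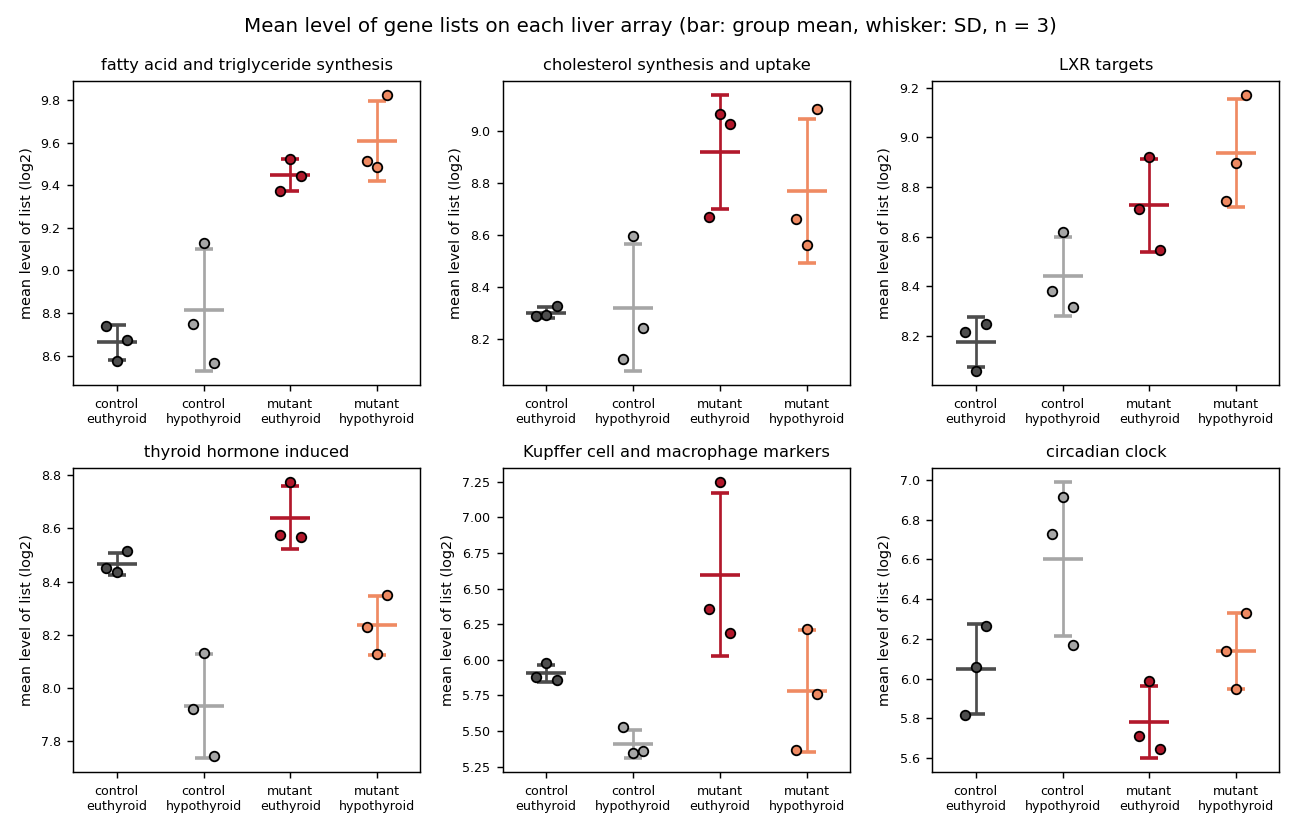
Mean log2 level of the members of 6 gene lists by group (points, arrays; bars, group means; whiskers, SD; n = 3 mice). Fatty acid and triglyceride synthesis averaged 8.66 and 8.82 in euthyroid and hypothyroid controls against 9.45 and 9.61 in the mutants.

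Other genes changed by the mutation in this average were more varied. The estrogen sulfotransferase Sult1e1 (3.16 ± 0.519, adjusted p = 0.00786), Sult2a3 (2.74 ± 0.365), Gm21286 (2.32), the fatty acid binding protein Fabp5 (2.14 ± 0.345, and 1.98 in another cluster) and the retinoic acid hydroxylase Cyp26a1 (2.01 ± 0.436) were, with Thrsp, the largest rises. Me1 (1.57 ± 0.157, and 1.70 in another cluster), Pdk4 (1.70 ± 0.249), Ehhadh (1.43 ± 0.151), Gpd2 (1.09 ± 0.147) and Ces2a (1.47 ± 0.0989) rose, as did the oxysterol hydroxylase Cyp7b1 (1.17 ± 0.191). Krt23 (-1.46 ± 0.164), Nr4a1 (-1.44 ± 0.263), Pcp4l1 (-1.31), the complement gene C8a (-1.26), Snora74a (-1.13), Snord104 (-0.93) and Flvcr2 (-0.90) fell. Pck1, the first enzyme of gluconeogenesis, fell by 0.83 ± 0.176 (adjusted p = 0.0338). Klf9, a thyroid hormone target, fell by 0.63 ± 0.144 (adjusted p = 0.0494) and the xenobiotic receptor Nr1i3 fell by 0.65 ± 0.14, whereas the receptors Ppard (0.76 ± 0.142) and Esr1 (0.63) rose. Dio1 (0.54, adjusted p = 0.103), Thra (-0.28) and Thrb (0.09) were not called. Genes induced by thyroid hormone passed as higher (camera adjusted p = 0.0396, and 0.33 with an estimated correlation), with 5 of 22 higher and 3 lower over all genes, and 7 and 6 adjusted over the list alone. Their p lay above 0.05 without control euthyroid replicate 13 (0.142), control hypothyroid replicate 20 (0.13), mutant euthyroid replicate 3 (0.109) or mutant hypothyroid replicate 7 (0.0747), and after quantile normalization (0.143). Xenobiotic metabolism (0.000337), oxidative phosphorylation (0.000903), PPARA targets (0.00444), female-biased genes (0.0124), bile acid genes (0.0217) and corepressor components (0.0412) passed as higher too, with adjusted p of 0.33, 0.45, 0.51, 0.33, 0.35 and 0.72 with an estimated correlation. By exact permutation of list means per mouse, their unadjusted p was 0.315, 0.025, 0.03, 0.235, 0.02 and 0.21 in the same order. None of them passed after adjustment over the lists. Without control euthyroid replicate 14 the p was 0.0685 for PPARA targets and 0.345 for corepressor components, which also failed without control hypothyroid replicate 20 (0.0647), mutant euthyroid replicate 3 (0.109) and mutant hypothyroid replicate 7 (0.21). After quantile normalization the p was 0.1 for PPARA targets and for oxidative phosphorylation, 0.166 for bile acid genes and 0.505 for corepressor components. Corepressor components turned direction with array SD as a covariate (0.0774). The p was then 0.0774 for genes induced by thyroid hormone, 0.122 for xenobiotic metabolism, 0.37 for oxidative phosphorylation, 0.445 for PPARA targets and 0.676 for bile acid genes. Of the called members, 2 of 8 induced by thyroid hormone (Thrsp and Me1), 1 of 5 in xenobiotic metabolism (Ces2a), 1 of 6 PPARA targets (Ehhadh) and 0 of 3 bile acid genes then stayed called. Bile acid genes gave 0.068 without mutant euthyroid replicate 3 and 0.0503 without mutant hypothyroid replicate 7, and female-biased genes 0.0651 without control hypothyroid replicate 17. Lists that did not pass were cell cycle (0.0577), genes repressed by thyroid hormone (0.065), exocrine pancreas (0.138), glucose metabolism (0.526), nuclear receptors (0.584), male-biased genes (0.616), lymphocyte markers (0.644), acute phase response (0.644), endoplasmic reticulum stress (0.776), endothelial (0.776), cholangiocyte (0.891) and stellate cell markers (0.891), and the growth hormone axis (0.902). In limma, 248 clusters of 237 genes were called, 197 higher and 51 lower (178 and 81 after quantile normalization, 222 and 27 after median centring, and 150 and 27 with a fold of at least 1.5). The count was 1866 without control euthyroid replicate 13 and 154 without replicate 15. It was 107 without control hypothyroid replicate 17 and 139 without replicate 18, 155, 158 and 145 without mutant euthyroid replicates 2, 3 and 4, and 144 and 149 without mutant hypothyroid replicates 6 and 7. It was 41 with array SD as a covariate, 25 higher and 16 lower, of which 32 were shared. Of 46 named calls, 27 were kept whichever array was left out. Those lost without at least 1 array were Klf9, Pck1, C8a, Cyp26a1, Lpl, Nr1i3, Esr1, Ppard, Hmgcs1, Per1, Adgre1, Snora74a, Snord104, Abcb11, Gadd45b, Cd36, Acot1, Pygl and Cyp3a11. The number lost was 11 without control euthyroid replicate 14 or 15, 18, 13 and 8 without control hypothyroid replicates 17, 18 and 20, 13, 6 and 14 without mutant euthyroid replicates 2, 3 and 4, and 9, 14 and 12 without mutant hypothyroid replicates 5, 6 and 7. The call of Klf9 was kept without control euthyroid replicate 13 or mutant euthyroid replicate 3 and lost without any other array.

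Hypothyroidism in control mice lowered some known targets of thyroid hormone, Dio1 and Gpd2 among them, and raised Serpina7, Lpl and Gstm3. Dio1 fell by 5.34 ± 0.21 (adjusted p = 2.71e-09), from 8.57 (SD 0.393, n = 3) to 3.23 (SD 0.02, n = 3), a level below the array medians; signal over background was not analysed here. Gpd2 fell by 1.62 ± 0.208 (adjusted p = 0.000755). Cyp7a1, the rate-limiting enzyme of bile acid synthesis, fell by 2.42 ± 0.447 (adjusted p = 0.014). Serpina7, which encodes thyroxine-binding globulin, rose 13.2-fold (3.72 ± 0.616, adjusted p = 0.00628), Lpl rose 8.96-fold (3.16 ± 0.39) and the glutathione transferase Gstm3 6.88-fold in one cluster (2.78 ± 0.148, adjusted p = 6.73e-08) and 4.3-fold in another (2.10 ± 0.141). Large falls were those of Gm21286 (-6.11 ± 0.528), Sult2a8 (-4.65 ± 0.407), 9030619P08Rik (-4.64 ± 0.238), A1bg (-4.35 ± 0.915), Sult5a1 (-3.75 ± 0.367), the carboxylesterase Ces3b (-3.11 ± 0.413) and the organic anion transporter Slc22a7 (-2.93 ± 0.272). Other large rises were those of Raet1d (3.22 ± 0.409), Krt23 (2.71 ± 0.232), Rgs16 (2.69 ± 0.476), Nr4a1 (2.68 ± 0.372) and Lgals1 (2.21 ± 0.318). The scavenger receptor Cd36 (1.85 ± 0.269), the nuclear receptor Pparg (1.37 ± 0.197), the coactivator Ppargc1a (1.26 ± 0.228, and 1.35 in another cluster), the pseudokinase Trib3 (1.20 ± 0.232) and the exporter Abcc3 (1.03 ± 0.131) rose. The cyclin Ccnd1 fell from 7.59 (SD 0.399) to 5.59 (SD 0.118, adjusted p = 0.00128). Thrsp (-0.73, adjusted p = 0.317), Me1 (0.12), Klf9 (-0.00), Thra (0.18) and Thrb (0.22) were not called. In limma, 242 clusters of 230 genes were called, 139 higher and 103 lower (141 and 160 after quantile normalization). All had groups that did not overlap, against 16.7% of all clusters and 10% by chance. A covariate for array SD gave 137 calls, 45 higher and 92 lower, of which 111 were shared, and with the compared groups alone 135. The count was 864 without control euthyroid replicate 13, and 134, 142 and 147 without control hypothyroid replicates 17, 18 and 20. Of 45 named calls, 25 were kept whichever array was left out. Those lost without at least 1 array were A1bg, Cyp7a1, Scd1, Scd2, Fads2, Gpam, Acox2, Gys2, Cyp3a11, Elovl3, Igfbp4, Cyp2d9, Cyp3a44, Igfals, Esr1, Trib3, Rgs16, Ppargc1a, Cyp27a1 and Stat5a, with 7 and 12 lost without control euthyroid replicates 14 and 15, and 13, 13 and 17 without control hypothyroid replicates 17, 18 and 20.

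In control mice, genes induced by thyroid hormone were lower in hypothyroid liver as a list (camera adjusted p = 0.00138, and 0.22 with an estimated correlation), with 5 of 22 lower and 1 higher, and 6 and 1 adjusted over the list alone. Female-biased genes fell as a list (1.93e-05, and 0.20 with an estimated correlation), with 3 of 11 lower, A1bg, Cyp3a44 (-1.74) and Cyp17a1 (-2.52 ± 0.335), and 5 adjusted over the list alone. Male-biased genes also passed as lower (0.0249, and 0.52 with an estimated correlation), with Nudt7 (-2.67 ± 0.214), Mup3 (-2.24) and Elovl3 (-2.17) among 3 that fell and Cyp2d9 (2.11) among 2 that rose, and 6 and 3 adjusted over the list alone. The growth hormone and IGF axis fell as a list (0.000858, and 0.20 with an estimated correlation), with 3 of 12 lower, Igfals (-0.91 ± 0.172), Stat5a (-0.76 ± 0.14) and Igfbp4 (-0.73), and 6 adjusted over the list alone. Kupffer cell markers were lower as a list (0.000368, and 0.52 with an estimated correlation), with 0 of 12 called, 1 adjusted over the list alone, and Clec4f (-0.90) and C1qc (-0.73) at the bottom. Acute phase genes were lower (0.0127, and 0.33 with an estimated correlation), with 0 called over all genes and 5 lower adjusted over the list alone. Clock genes were higher (0.000115, and 0.33 with an estimated correlation), with 0 called, 4 adjusted over the list alone, and Ciart (1.44, adjusted p = 0.0761) at the top. Xenobiotic metabolism passed as higher (0.00891, and 0.52 with an estimated correlation), with 3 of 23 higher, Gstm3, Nqo1 (1.94 ± 0.151) and Gstm1 (1.14 ± 0.128), 1 lower, Cyp3a11 (-0.92), and 7 and 2 adjusted over the list alone. Its mean difference was 0.095 and its median -0.000823. Corepressor components (0.00449), LXR targets (0.0127), glucose metabolism (0.024) and endothelial markers (0.0479) passed as higher, with adjusted p of 0.56, 0.52, 0.52 and 0.56 with an estimated correlation. Without control euthyroid replicate 14 the p of corepressor components was 0.246 and that of glucose metabolism 0.0595, and without control euthyroid replicate 15 that of acute phase genes was 0.0933, of xenobiotic metabolism 0.0664 and of glucose metabolism 0.0635. Without control hypothyroid replicate 18 it was 0.0576 for LXR targets, 0.173 for glucose metabolism and 0.0594 for male-biased genes, and without control euthyroid replicate 13 that of male-biased genes was 0.228. The p of endothelial markers was 0.129 and 0.103 without control euthyroid replicates 14 and 15, 0.159 and 0.0594 without control hypothyroid replicates 17 and 18, 0.0509 and 0.0533 without mutant euthyroid replicates 3 and 4, and 0.0553 without mutant hypothyroid replicate 7. After quantile normalization the p was 0.0604 for LXR targets and for xenobiotic metabolism, 0.133 for endothelial markers and 0.211 for glucose metabolism. Array SD averaged 2.29 in hypothyroid and 2.26 in euthyroid controls. Of the called members, 3 of 6 induced by thyroid hormone, 1 of 3 female-biased (Cyp17a1), 3 of 5 male-biased, 0 of 3 growth hormone genes, 1 of 3 LXR targets and 3 of 4 in xenobiotic metabolism stayed called with it as a covariate. The p was then 0.433 for xenobiotic metabolism, 0.541 for LXR targets, 0.254 for glucose metabolism and 0.94 for corepressor components, which turned direction, and for endothelial markers.

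Hypothyroidism in mutant mice changed many of the same genes. Dio1 fell by 6.37 ± 0.21 (adjusted p = 2.04e-10), from 9.62 (SD 0.113, n = 3) to 3.25 (SD 0.449, n = 3), again below the array medians. Serpina7 rose 14.8-fold (3.89 ± 0.616) and Gstm3 4.65-fold in one cluster (2.22 ± 0.148) and 3.41-fold in another (1.77 ± 0.141). Cyp4a12b (5.25 ± 0.72) and Cyp4a12a (5.20 ± 0.994), male-biased fatty acid hydroxylases with similar sequences, rose most. Nox4, an NADPH oxidase, rose by 2.09 ± 0.388, Rgs16 by 2.17, Etnppl by 2.05 ± 0.189, Lpl by 2.02 ± 0.39, Scd2 by 1.70 ± 0.183 and Pparg by 0.99 ± 0.197. The largest falls beside Dio1 were those of Gm21286 (-8.57 ± 0.528), Cyp3a16 (-6.02 ± 0.956), 9030619P08Rik (-5.65 ± 0.238), A1bg (-4.54 ± 0.915), Ugt2b37 (-4.50 ± 0.486), Sult5a1 (-3.63 ± 0.367) and the elongase Elovl3 (-3.25 ± 0.435). Ccnd1 fell by 2.36 ± 0.275 and Pnpla3 fell by 1.85 ± 0.248. Gpd2 (-0.63, adjusted p = 0.18), Thrsp (-0.63), Me1 (0.15), Klf9 (0.03), Thra (0.21) and Thrb (0.18) were not called. In limma, 241 clusters of 234 genes were called, 142 higher and 99 lower (111 and 121 after quantile normalization). All had groups that did not overlap, against 25.7% of all clusters and 10% by chance. The count was 366 and 620 without control euthyroid replicates 13 and 14, 121 and 95 without mutant euthyroid replicates 2 and 4, and 158, 151 and 89 without mutant hypothyroid replicates 5, 6 and 7. It was 36 with array SD as a covariate, 10 higher and 26 lower, of which 31 were shared. Of 36 named calls, 18 were kept whichever array was left out. Those lost without at least 1 array were Clec4f, Ephx1, Cyp2d9, Rgs16, Idh3a, Mup3, Fads2, Cyp4a12a, Nox4, Lpl, Pgd, Gadd45b, Igfals, Stat5a, Pparg, Esr1, Saa2 and A1bg, with 17, 9 and 13 lost without mutant euthyroid replicates 2, 3 and 4, and 13, 12 and 15 without mutant hypothyroid replicates 5, 6 and 7.

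Among the lists in mutants, xenobiotic metabolism rose with hypothyroidism (camera adjusted p = 3.17e-08, and 0.34 with an estimated correlation). Of its 23 genes 6 rose, among them Nqo1 (1.72 ± 0.151), Gadd45b (1.27 ± 0.255) and Ephx1 (1.11 ± 0.25), 0 fell, and 9 were higher adjusted over the list alone. Of the 6, Gstm3, Gstm1 and Nqo1 stayed called after quantile normalization, without both outlying arrays and with array SD as a covariate, whereas Gadd45b (0.0505, 0.0644 and 0.513) and Ephx1 (0.0929, 0.0784 and 0.525) were lost in each. Kupffer cell markers fell as a list (6.07e-08, and 0.34 with an estimated correlation), with 1 of 12 called, Clec4f (-1.06 ± 0.242, adjusted p = 0.0489), and 11 adjusted over the list alone. The call of Clec4f was kept without control euthyroid replicate 13 or 14, mutant euthyroid replicate 4 or mutant hypothyroid replicate 6. It was lost without any other single array, without both outlying arrays (0.142) and with array SD as a covariate (0.0926). Cell cycle genes fell (7.16e-07, and 0.34 with an estimated correlation), with Ccnd1 the 1 call of 19 and 9 adjusted over the list alone. Female-biased genes fell (1.08e-05, and 0.34 with an estimated correlation), with 3 of 11 lower, Cyp3a16, A1bg and Cyp17a1 (-2.67 ± 0.335), and 4 adjusted over the list alone. The growth hormone and IGF axis fell (0.0238, and 0.34 with an estimated correlation), with Igfals (-0.87 ± 0.172) and Stat5a (-0.69) lower of 12, and its p was 0.0609 without mutant euthyroid replicate 3 and 0.129 without mutant hypothyroid replicate 5. Glucose metabolism (0.00324) and clock genes (0.00819) passed as higher with 0 called, and their adjusted p was 0.37 and 0.44 with an estimated correlation. Corepressor components (0.0111), LXR targets (0.0234), endothelial markers (0.036) and fatty acid synthesis (0.0435) passed as higher, with adjusted p of 0.55, 0.48, 0.54 and 0.57 with an estimated correlation, and of the fatty acid genes 3 rose and 2 fell. Without mutant hypothyroid replicate 7 the p was 0.0925 for corepressor components, 0.124 for LXR targets and 0.286 for fatty acid synthesis. Without mutant euthyroid replicate 4 it was 0.102 for LXR targets and for endothelial markers. For endothelial markers it was 0.664 without mutant hypothyroid replicate 6 and 0.0643 without control euthyroid replicate 14. For fatty acid synthesis it was 0.0555, 0.0661 and 0.0504 without control euthyroid replicates 13, 14 and 15, and 0.0563 and 0.095 without mutant euthyroid replicates 2 and 4. Genes induced by thyroid hormone did not pass (0.0744), with 2 of 22 lower, Dio1 and Idh3a (-0.80 ± 0.168), and, adjusted over the list alone, 5 lower and 3 higher. After quantile normalization the p was 0.13 for LXR targets and for endothelial markers, 0.167 for corepressor components and 0.236 for fatty acid synthesis. Array SD averaged 2.34 in hypothyroid and 2.28 in euthyroid mutants. Of the called members, 0 of 3 female-biased genes, 0 of 2 growth hormone genes and 1 of 5 in fatty acid synthesis (Scd2) stayed called with it as a covariate. LXR targets (0.984), endothelial markers (0.808) and corepressor components (0.0748) then turned in direction. The p was then 0.555 for fatty acid synthesis, 0.172 for glucose metabolism and 0.053 for clock genes.

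**Figure D2:**
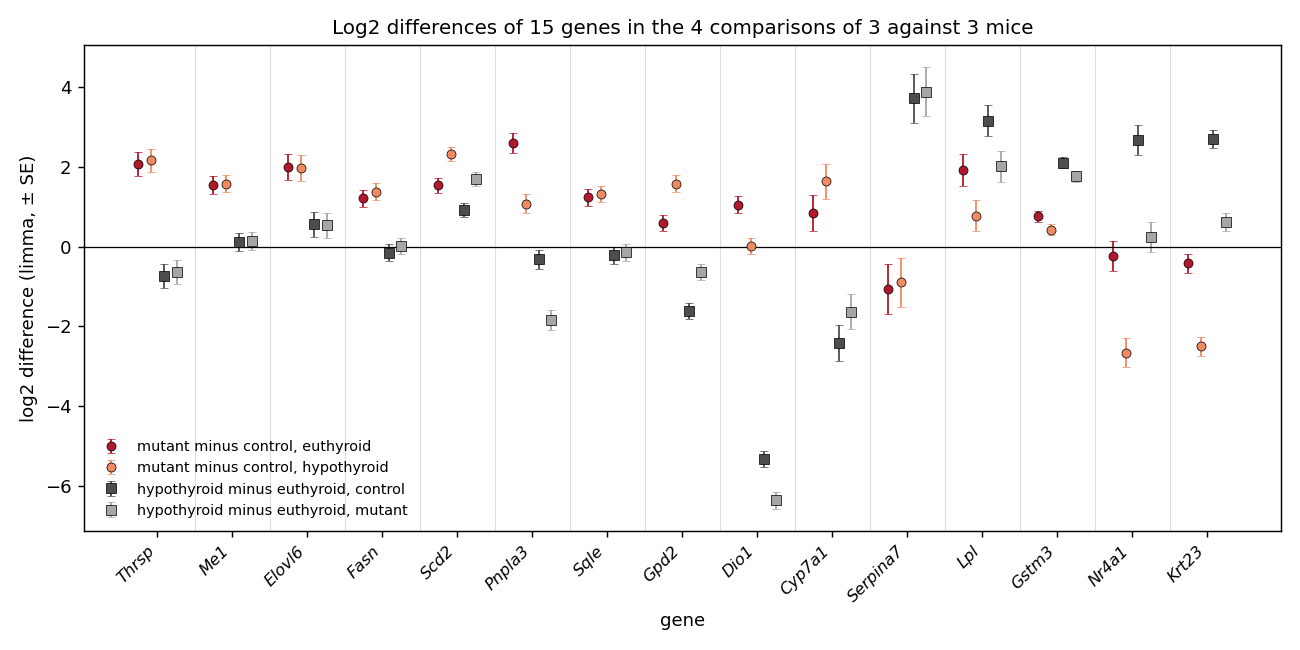
Log2 difference of 15 genes in 4 comparisons (points, limma estimate; bars, SE; n = 3 mice per group). Dio1 fell by 5.34 in control and by 6.37 in mutant mice with hypothyroidism, to levels below the array medians, while Thrsp rose by 2.07 and 2.16 with the mutation in euthyroid and hypothyroid mice.

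The 4 comparisons were then set against each other. Of the clusters called higher in mutants, 13 of 11 genes were shared by both thyroid states (Ces2a, Ehhadh, Elovl6, Fasn, Gask1a, Me1, Scd2, Sqle, Sytl5, Thrsp and Vtcn1), against 0.0582 for independent lists. Gask1a, Sytl5 and Vtcn1 lie outside the rule for naming genes and are given here as members of this overlap. The mutant effects of the 2 states correlated across genes (Pearson r = 0.545, Spearman rho = 0.481), with a covariance of 0.0322. Without control euthyroid replicate 14, r was 0.311. The covariance in simulations of unchanged groups (8.27e-05) was near 0 by construction. These effects share no arrays and the simulated noise was independent, so that value lends no support. With hypothyroidism, 69 clusters were higher and 58 lower in both genotypes (0.906 and 0.468 for independent lists), and r was 0.703 (rho = 0.606, covariance 0.0637). The difference of the mutant effect between thyroid states called 0 clusters in limma (600 at an unadjusted p under 0.05, 1089 by chance, 0 with a variance trend and 8 with array weights). Dio1 (-1.04 ± 0.297), Gpd2 (0.99 ± 0.294), Pnpla3 (-1.52 ± 0.351) and Cyp3a11 (1.31 ± 0.27) each had an adjusted p of 1 there; for Dio1 the value rests on hypothyroid levels below the array medians. Leaving out 1 array made 1 call in each of 3 cases. These were Krt23 (-2.39 ± 0.26, adjusted p = 0.00415) without control euthyroid replicate 13, Sult2a8 (3.79 ± 0.374, adjusted p = 0.00217) without control hypothyroid replicate 18, and Nr4a1 (-3.02 ± 0.336, adjusted p = 0.00958) without replicate 20.

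By median, genes that hypothyroidism lowered in controls lay higher in mutants than in controls in both thyroid states. The arrays were too few for the exact test to pass. Of the 103 clusters lower in hypothyroid controls, 14 were higher in hypothyroid mutants, among them Cyp27a1, Cyp3a11, Gpd2, Paqr9, Rarres1 and Sult2a8 (0.222 for independent lists), and of the 139 that were higher, Krt23, Nr4a1 and Zfp395 were lower in hypothyroid mutants (0.0638). As many of the 139, 3 clusters of Scd2 and Sytl5, were higher in hypothyroid mutants (0.3). In euthyroid mutants 4 of the 103 and 6 of the 139 were higher (0.128 and 0.172). The comparisons with hypothyroid mutants share the hypothyroid controls, and those with euthyroid mutants share the euthyroid controls. Part of either excess may come from these shared arrays. Across all genes, r with the effect in hypothyroid mutants was -0.07 against -0.50 in simulations, and the covariance exceeded the simulated one by 0.0124. With the effect in euthyroid mutants r was 0.263 against 0.5 in simulations, and the covariance exceeded the simulated one by 0.000701. A positive excess means that, beyond the shared arrays, genes tended to change in the same direction with hypothyroidism and with the mutation. Across all genes these values thus show no reversal, and they lend no support to one among the genes that hypothyroidism lowered. The cause of the excess was not tested. In the cross-fitted measure, which separates the arrays that pick from those that measure, the picked lower genes were higher in hypothyroid mutants by a median of 0.43 (SD 0.132 over the 3 arrays left out). For the mean over these genes the exact permutation p was 0.1, the smallest possible with 3 against 3. On average 67.3 genes were picked and 87.8% of them were higher; the range over the arrays was 0.30 to 0.56. In euthyroid mice the same measure was 0.29 (SD 0.141, exact permutation p = 0.3), and the difference between the thyroid states was not tested. The measure was not run after quantile normalization or with array SD as a covariate. Array SD averaged 2.34 in hypothyroid mutants and 2.29 in hypothyroid controls, so a part of the signal range in these values stays open. Genes that hypothyroidism raised in controls differed by 0.02 (SD 0.0419, exact permutation p = 1) in hypothyroid and by -0.03 (SD 0.159, exact permutation p = 1) in euthyroid mutants.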

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

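The tests of a fed state, of fewer hepatocytes and of the time of day, the splits of the difference between thyroid states, the fits without both outlying arrays and with array SD as a covariate, and the permutation of list means per mouse were chosen after the results were seen.

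A difference of the mutant effect between thyroid states was found by test in 3 gene lists, with 0 of their genes called. Xenobiotic metabolism rose more with the mutation in hypothyroid than in euthyroid mice (mean 0.27, 16 of 23 genes positive, camera adjusted p = 0.00905). Its adjusted p was 0.284 without control euthyroid replicate 13, 0.181 without control hypothyroid replicate 17, 0.239 without mutant euthyroid replicate 4 and 0.076 without mutant hypothyroid replicate 7, and 0.157 with array SD as a covariate. Cell cycle genes were lower in that difference (mean -0.33, camera adjusted p = 1.93e-05), with an adjusted p of 0.0662 without mutant euthyroid replicate 4. Kupffer cell and macrophage markers were lower in it as well (mean -0.32, 12 of 12 genes, camera adjusted p = 0.042). Their adjusted p was 0.151, 0.0675 and 0.0877 without control euthyroid replicates 13, 14 and 15, 0.17 without control hypothyroid replicate 17, 0.58 and 0.0828 without mutant hypothyroid replicates 5 and 7, and 0.898 in the opposite direction without mutant euthyroid replicate 3. With an estimated correlation the adjusted p of each of the 3 was 0.89, and with the averaged mutant effect taken out 84 of 100 splits of the samples within thyroid state gave as many lists as these 3 (highest other 16), so chance is not excluded. Outside the clusters with 1 gene symbol, 13 clusters were higher in hypothyroid mutants than in hypothyroid controls, 12 with no listed gene and 1 with several symbols, against 0 in euthyroid mice; whether those counts differ was not tested.

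Genes of fatty acid and triglyceride synthesis were higher in every mutant than in every control by list mean (camera adjusted p = 9.91e-24, and 0.074 with an estimated correlation). Against a wider signal range of the mutant arrays as the whole cause, the list's median difference after quantile normalization was 0.56, at percentile 100 of 10000 lists of like level. With array SD as a covariate the list kept its call (camera adjusted p = 2.38e-22), while 6 of its 14 called genes stayed called (Fasn, Pnpla3, Scd2, Elovl6, Thrsp and Me1). A more fed state of the mutants cannot be told apart from an effect of the mutation, since fasting-induced genes went both ways (mean -0.00375 ± 0.133 SE, exact permutation p = 0.97) and feeding is not given in the sources used here. An effect of the altered corepressor on these genes is the difference the design names and stays open as a hypothesis.

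Macrophage markers were higher in mutants as a list (camera adjusted p = 1.14e-07 averaged over thyroid states, and 0.33 with an estimated correlation), with list means of 6.60 (SD 0.571) and 5.78 (SD 0.426) in euthyroid and hypothyroid mutants against 5.91 (SD 0.0622) and 5.41 (SD 0.0998) in controls, and mutant euthyroid replicate 3 was highest at 7.25. A lower share of hepatocytes would raise the markers of other cells alike, but endothelial markers differed by 0.0388 ± 0.114 SE (exact permutation p = 0.745). Macrophage minus endothelial markers differed by 0.493 ± 0.146 SE (exact permutation p = 0.005), which argues against it as the whole cause. Both list results were known when this difference was chosen, so its p is no separate support. Signal range as the whole cause is argued against by a median of 0.44 after quantile normalization, at percentile 100 of lists of like level. In hypothyroid mice alone the list's call ended with array SD as a covariate (camera adjusted p = 0.847). The size of the difference in that fit is not given here, so a smaller difference cannot be told from a less precise one. There the signal range stays open. More macrophages, or higher levels of these genes in each, may account for the rest, and no test here separates them.

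Clock genes were lower in mutants as a list (camera adjusted p = 0.000796, and 0.33 with an estimated correlation), with Per1 the 1 call. That call ended without both outlying arrays (adjusted p = 0.0519), with array SD as a covariate (0.166), and without any 1 of control euthyroid replicate 14 (0.0608), control hypothyroid replicates 17 (0.0888) and 18 (0.0625), mutant euthyroid replicates 2 (0.067) and 4 (0.0512) or mutant hypothyroid replicates 5 (0.0613) and 6 (0.0781). Signal range as the whole cause is argued against by a median of -0.53 after quantile normalization, at percentile 0 of lists of like level. A shift of the time of day would also move genes that peak in the opposite phase the other way. Their mean was higher in mutants by 0.572 ± 0.242 SE (exact permutation p = 0.03), by 0.491 in euthyroid and 0.654 in hypothyroid mice, with 0 of the 4 genes called. A difference in the time of day of sampling may account for the pattern, and the sampling times are not given in the sources used here. An effect of the mutation on the clock itself would show the same values, so it stays open and was not tested.

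Other splits of the samples were counted for each comparison. With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. For mutant against control the real split gave 28 calls in euthyroid and 57 in hypothyroid mice (highest other 1 and 0), and for hypothyroid against euthyroid 242 in controls and 241 in mutants (highest other 1 and 0). For lists the real split gave 10, 10, 12 and 11 (highest other 9, 11, 8 and 12), and 1, 2, 1 and 3 of the splits gave as many, the real one included. Of 100 splits drawn within thyroid state, 2 gave as many calls as the 248 of the averaged mutant effect, 3 as many lists (12, highest other 12) and 2 as high a correlation of the mutant effects (0.545, highest other 0.574), the real one included. These shares lie under 0.05 in this draw, which makes chance unlikely but does not exclude it. The 1 split with more calls, 669, exchanged control euthyroid replicate 13 with mutant euthyroid replicate 2 and so points to a structure of the samples. Replicates of the euthyroid controls correlated least within their group (0.9683 between 13 and 14). Of the exchanged arrays, control euthyroid replicate 13 correlated at 0.9836 with mutant euthyroid replicate 3 and at 0.9819 with control euthyroid replicate 15. Mutant euthyroid replicate 2 correlated at 0.9856 with control euthyroid replicate 15, and at 0.9848 and 0.9847 with mutant euthyroid replicates 3 and 4. The genotype labels could not be checked by the level of Ncor1, and what sets these arrays apart was not tested. The correlation of the thyroid effects (0.703, highest other 0.587) was reached by 1 of 100 splits drawn within genotype, the real one, a share under 0.05 in this draw. For the difference between thyroid states the real count of calls was 0, which 100 of 100 splits reach by construction (highest other 3), so the splits say nothing there.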

How the results depend on the processing

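The fits without both outlying arrays and with array SD as a covariate were chosen after the data were seen. No paired analysis was possible because the groups share no replicate numbers. The 168 called values of named genes were refitted under the alternatives, which gave 3639 values. Of these, 757 were no longer called, 2882 were still called, and 0 turned direction. Median centring, a fold limit of 1.5 and a variance trend with robust moderation kept each total of calls within 1.5 times, but not each direction. Calls that were lower went from 10 to 5 with median centring for the mutant effect in hypothyroid mice. For the averaged effect they went from 51 to 27 with median centring and to 27 with the fold limit; the cause was not tested. The limit that arrays set is their number, and signal over background was not analysed here.

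Counts stand in the order mutant effect in euthyroid mice, in hypothyroid mice, hypothyroidism in controls, in mutants, and averaged mutant effect. The 28, 57, 242, 241 and 248 calls became 2733, 515, 5680, 827 and 3439 with array weights, and the difference between thyroid states went from 0 to 8. The weights put 29.2 on control euthyroid replicate 15 and did not reach their tolerance. With every cluster of the table the calls became 10, 33, 144, 146 and 95. That fit has more tests and moderates the variances over all clusters, and the cause of the change was not tested. Quantile normalization gave 45 in euthyroid mice. With the compared groups alone the mutant effect in hypothyroid mice gave 174 and hypothyroidism in controls 135. Without both outlying arrays, which leaves fewer samples, the euthyroid mutant effect gave 14 and the averaged one 140. With array SD as a covariate the hypothyroid mutant effect gave 9, hypothyroidism in controls 137 and in mutants 36, and the averaged effect 41. Leaving out each array in turn gave 6 to 192, 21 to 133, 134 to 864, 89 to 620 and 107 to 1866 calls, and 0 to 1 for the difference between thyroid states; the cause was not tested.

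Of lists past the threshold (10, 10, 12, 11 and 12, and 3 for the difference), clusters above the median level gave 5, 6, 6, 7 and 6, and 1, with fewer genes tested. Quantile normalization gave 6 in euthyroid mice, and the fit without both outlying arrays 6. An estimated correlation gave 0 in each comparison, and fry, which tests another hypothesis, gave 2, 1, 3, 5 and 4, and 0. Leaving out each array gave 7 to 11, 8 to 12, 8 to 13, 9 to 14 and 10 to 13, and 1 to 5. With array SD as a covariate 5 lists turned direction, corepressor components with hypothyroidism in controls (adjusted p = 0.94), in mutants (0.0748) and with the mutation (0.0774), and with hypothyroidism in mutants LXR targets (0.984) and endothelial markers (0.808). Without mutant euthyroid replicate 3, Kupffer cell markers did so for the difference between thyroid states (0.898, in a range of 1.13e-05 to 0.898 over single arrays left out). The cause was not tested.

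The correlation of the thyroid effects was 0.897 over genes called in either comparison, which are chosen for large changes, 0.549 without both outlying arrays, and 0.557 to 0.734 over single arrays left out; that of the mutant effects was 0.311 to 0.626. The mutant effect on genes lower in hypothyroid controls was 0.287 with 200 genes by fold in hypothyroid mice, and ranged from 0.30 to 0.563 in hypothyroid and from 0.164 to 0.443 in euthyroid mice over single arrays. On genes higher in hypothyroid controls it was -0.163 in hypothyroid mice when picked and measured on the same arrays, which share their errors, and -0.134 without both outlying arrays. It ranged from -0.00744 to 0.0677 in hypothyroid and from -0.14 to 0.149 in euthyroid mice; the cause was not tested. The planned level of Ncor1 was not run, as no cluster carries that name.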

Other observations

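No test in this part was chosen after its result was seen. Among genes that thyroid hormone represses, 2 of 7 rose with hypothyroidism in controls, Serpina7 (3.72 ± 0.616, adjusted p = 0.00628) and the desaturase Scd1 (0.82 ± 0.174, adjusted p = 0.0326), while Cyp17a1, a steroid hydroxylase, fell by 2.52 ± 0.335. The list did not pass (camera adjusted p = 0.342). In mutants 1 of 7 rose and 1 fell, Serpina7 and Cyp17a1 (camera adjusted p = 0.629). Of 22 nuclear receptors, Pparg rose (1.37 ± 0.197 in controls and 0.99 ± 0.197 in mutants) and Esr1, an estrogen receptor, fell by 0.83 ± 0.181 in controls and fell by 0.90 in mutants. That list did not pass with hypothyroidism (camera adjusted p = 0.186 and 0.151). Bile acid genes did not pass with hypothyroidism in controls (camera adjusted p = 0.055), with Cyp7a1 and Cyp27a1 lower and Abcc3 and Acox2 higher. After quantile normalization 7 were lower and 1 higher, Acox2 being lost (adjusted p = 0.113). The call of Acox2 was kept without control euthyroid replicate 14 or mutant euthyroid replicates 3 or 4 and lost without any other single array. Of the stress genes, Trib3 rose in hypothyroid controls (1.20 ± 0.232, adjusted p = 0.0192), and metallothionein Mt2 differed by -1.80 ± 0.61 with the mutation (adjusted p = 0.168) and was not called.

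Markers of other cells were also measured. Averaged over thyroid states, lists of stellate, endothelial, cholangiocyte, lymphocyte and exocrine pancreas markers did not pass (camera adjusted p 0.891, 0.776, 0.891, 0.644 and 0.138). The erythroid genes Alas2 (5.58 to 7.10) and Slc4a1 (4.03 to 4.69), and the adipocyte genes Adipoq (2.02 to 2.49), Plin1 (3.66 to 4.94) and Retn (3.22 to 3.82), were measured without a list test. None was called in the averaged mutant effect, where limma gave adjusted p of 0.707, 0.635, 0.785, 0.387 and 0.404. Of clusters with several symbols or none, 31 were called with hypothyroidism in controls, 30 in mutants, and 11 in the averaged mutant effect, out of 13768 tested.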
